A study of Caenorhabditis elegans with 12 samples.

How the data were processed

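Small RNA was measured by RIP-seq, the sequencing of RNA recovered with an immunoprecipitated protein, in staged L4 whole worms grown at 15 °C. Each of 4 groups had 3 libraries lettered A, B and C: CSR-1 input, CSR-1 IP, WAGO-1 P3G input and WAGO-1 P3G IP. The IPs used an antibody against FLAG. Per the labels, small RNA of the inputs was enriched with a kit from 500 ng of total RNA, and that step was left out for the IPs. All RNA was treated with an RNA 5' polyphosphatase, made into libraries with a microRNA library kit and read for 50 cycles, single end. For some samples the opening text of the description contradicts the title. The title, the sample name within the description and the antibody field matched each other and set the groups.

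The deposited table holds raw counts, with no normalization, for 20134 WormBase gene identifiers, 55259 intervals named by chromosome, start, end and strand, and 5 summary entries. HTSeq 0.11.2, cutadapt 2.3, Bowtie 1.2.3 and SAMtools 1.9 and the build ce11 are credited to the submitters' processing notes, which state no role or order. The aligner settings, the strand setting, the treatment of reads with several alignments and the annotation behind the intervals are not given in the sources used here. The table's entry for reads with no unique alignment is 0 in every library, as are those for low quality and unaligned reads. Intervals with near-identical copies elsewhere are therefore of uncertain origin. Total counts were taken as all counts of a library, the entries for no feature and ambiguous reads included, and counted reads as those on identifiers and intervals.

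No table pairing identifiers with symbols was at hand, and 0 identifiers were matched. Intervals were given the RefSeq genes of WBcel235 that they overlap, on either strand, and 5 classes: no RefSeq gene, protein-coding, pseudogene, other noncoding, and structural or short RNA gene. Lists were written before the data were examined, as were the comparisons, tests and alternatives except where said. They were used on intervals overlapping their genes. Of the 52 tested intervals of the structural or short RNA class, 23 lay within a RefSeq gene of any class and 29 within none. How many lay within a structural or short RNA gene itself was not counted. Tested intervals numbered 2 for germ granule and germline small RNA factors, 5 for meiotic prophase, 1 for oogenesis and maternal, 2 for DNA replication and mitosis, 1 for cytosolic ribosomal proteins, 1 for ERGO-1 class targets, 4 for published WAGO silenced genes, 2 for cuticle and hypodermis and 1 for neurons. They numbered 0 for spermatogenesis, histones, muscle, intestine and transposons, so these lists gave no test. Lists were matched by gene symbol, so intervals that are themselves transposon copies, if any, would not be found this way. The neuron interval, in ric-4, and those in cdt-1 and col-136 were not called in any comparison when adjusted over all features. Adjusted over the list alone, 2 of 2 cuticle and hypodermis intervals were higher in the difference, col-136 among them (log2 2.03 ± 0.96), and 12 of 26 alternatives also called it there.

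Differential recovery was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors and quasi-likelihood F tests, fitted on all 12 libraries with a mean per group and 8 residual degrees of freedom. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over the 10822 tested, of which 1286 were intervals. The difference of enrichments was the contrast of the log2 IP over input of each strain. The p-values measure the spread between these samples only, and the labels do not say whether replicates were separate cultures. Sets with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, preset correlation 0.01, over 40 tests. With an estimated correlation 10 of the 40 passed, against 37 with the preset one. Intervals as a class differ from identifiers, so after these values were seen each set was also tested against the other intervals alone, over 36 tests. The meiotic prophase list had passed against all features in all 4 comparisons with the preset correlation (adjusted p = 0.00217 to 0.0183) and in none with an estimated one (0.106 to 0.161). It passed in none against the other intervals. The rotation test fry, which asks whether a set's members move on balance in 1 direction, was an alternative. Shares were compared by exact permutation, 2-sided, and overlaps by Fisher's exact test.

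Named features were taken by rule: past the threshold, with a mean of at least 20 CPM over the 12 libraries and the compared libraries not overlapping, those with the largest and smallest log2. The rule was applied apart to intervals (6 and 6, or 4 and 4 for the inputs) and to identifiers (2 and 2), a split decided once the table was seen. To these were added up to 4 called members per list. Features outside the rule are given with the statement that their values had been seen, or stand beside their values in another comparison. Ratios for features with 1 to 3 counts carry a 95% counting interval on summed counts, which covers counting error only, since reads without molecular identifiers are not independent molecules.

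Tested on simulated data with the group depths of these libraries, edgeR recovered 81, 66, 50 and 59 of 100 features changed 2-fold in the CSR-1 IP, WAGO-1 P3G IP, difference and input comparisons, and 99, 100, 94 and 94 of 100 changed 4-fold. False calls were 2.17%, 2.92%, 5.88% and 5.56%. Camera called the raised set of 100 in each comparison and 0 of 20 unchanged sets. The simulation changed few features, as many up as down and all at 20 CPM or more, and drew each feature independently. It therefore did not test the scaling when many features change, as here, or sets whose members are correlated. Recovery was thus lower for 2-fold than for 4-fold changes, and depth was not varied. The inputs are the shallow side of each comparison. Replicates correlated at r = 0.875 to 0.994 across features, and pairs of replicates differed by 1.16 to 7.95 times the chi-square of sampling noise per degree of freedom. The largest, 7.95 and 6.70, were CSR-1 IP replicate A against B and C.

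The alternatives were median-of-ratios factors, library totals, no filter, at least 5 CPM in 3 libraries, DESeq2 1.42.0, the replicate letter as a block, only the libraries compared, structural and short RNA intervals left out, a 2-fold minimum, and each library left out in turn. Added after seeing the data were thinning of all libraries to 334088 counted reads and the omission of both CSR-1 libraries lettered A. Length bins of under 200 bp, from 200 bp to under 1000 bp, and 1000 bp or more were also added as sets then. Leaving out or thinning libraries moves the filter's cutoff, which follows the median library size. The first values were obtained with the filter run again, and after these were seen the tested features were held to those of the full fit, so that a single choice changed. Values with the filter run again were kept as added alternatives. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used for tables and plots. No deposited library was left out.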

Results

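Small RNAs were sequenced from whole Caenorhabditis elegans animals at the L4 larval stage, before and after immunoprecipitation (IP) of a FLAG-tagged Argonaute protein, the protein family that carries small RNAs to their targets. The 12 libraries fell into 4 groups of 3. CSR-1 input and CSR-1 IP came from animals with FLAG-tagged CSR-1, an Argonaute whose small RNAs are mostly antisense to germline-expressed genes. WAGO-1 P3G input and WAGO-1 P3G IP came from animals with a FLAG-tagged WAGO-1, an Argonaute of silencing pathways, that carries the P3G change, and with a WAGO-3 that carries P2G and A3E. Residue numbers are those of the labels. Bait, tag and genotype therefore differed together, and an IP of unmodified WAGO-1 was not among these libraries. The series title names protease-mediated processing of Argonautes and its effect on small RNA association as its subject.

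Read totals were 878241 to 1373120 per input library, 3321443 to 6131378 per CSR-1 IP library and 10952884 to 13473204 per WAGO-1 P3G IP library. Reads counted to a feature were 334088 to 533232 per input and 2405005 to 9187525 per IP. The features were 20134 WormBase gene identifiers and 55259 genomic intervals with a strand, on build ce11. The identifiers could not be paired with gene symbols, so csr-1, wago-1, wago-3 and dpf-3 were not matched, and identifiers are named as given. The intervals are placed by their coordinates and by the RefSeq genes they overlap on either strand. An interval said to be in a gene may extend past it, and some hold a short gene whole. Whether an interval lies in an exon or an intron is unknown here. The annotation that defines the intervals is also not given, so reads on an interval in a gene need not come from that gene. Levels are CPM, counts scaled to the reads counted in the library, as mean ± SD with n = 3 libraries per group. Fold changes come from the edgeR fit, which also scales for composition. The SE given is the size of the log2 fold change divided by the square root of its F statistic. It is thus an approximation and not an SE estimated by the fit. The fitted fold was at the median 1.34 times the ratio of CPM for the CSR-1 IP, 1.51 times for the WAGO-1 P3G IP and 0.945 times for the inputs. For 160 features called higher in the WAGO-1 P3G IP, 24 of them intervals, and 19 called higher in the CSR-1 IP, mean CPM was lower in the IP. Where 1 to 3 counts are given, ratios are of counts scaled to counted reads alone, and the fitted fold stands beside them if it differs by over 1.4 times. Features given as largest or steepest are those among features with a mean of at least 20 CPM over the 12 libraries and no overlap between the groups compared. Some called changes outside these limits were larger.

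Genomic intervals held 15.4% ± 1.01 of counted reads in the CSR-1 inputs and 3.70% ± 0.673 in the CSR-1 IPs (SD, n = 3 each). In the WAGO-1 P3G strain the share went the other way, from 8.09% ± 0.102 in the inputs to 11.06% ± 0.119 in the IPs (SD, n = 3 each). Before any IP, the interval share of the WAGO-1 P3G inputs was 0.526 of that of the CSR-1 inputs. As shares of all reads the sizes differed: 0.328 for that ratio, 3.48 for WAGO-1 P3G IP over input (1.37 of counted reads) and 0.421 for CSR-1 IP over input (0.241 of counted reads). Reads on no feature made up 56.9% ± 2.81 of totals in CSR-1 inputs, 24.5% ± 4.06 in CSR-1 IPs, 73.3% ± 0.734 in WAGO-1 P3G inputs and 31.9% ± 0.309 in WAGO-1 P3G IPs. The 10 most abundant features of each library took 16.4% of counted reads in the WAGO-1 P3G IPs and 4.90% in the CSR-1 IPs. None of these groups overlapped, and each 2-sided exact permutation test gave p = 0.1 (24 tests, Benjamini-Hochberg p = 0.1), the smallest that 3 against 3 allows. CSR-1 IP replicate A stood apart from its group, with an interval share of 2.94% against 4.19% and 3.99% in replicates B and C.

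**Figure D1:**
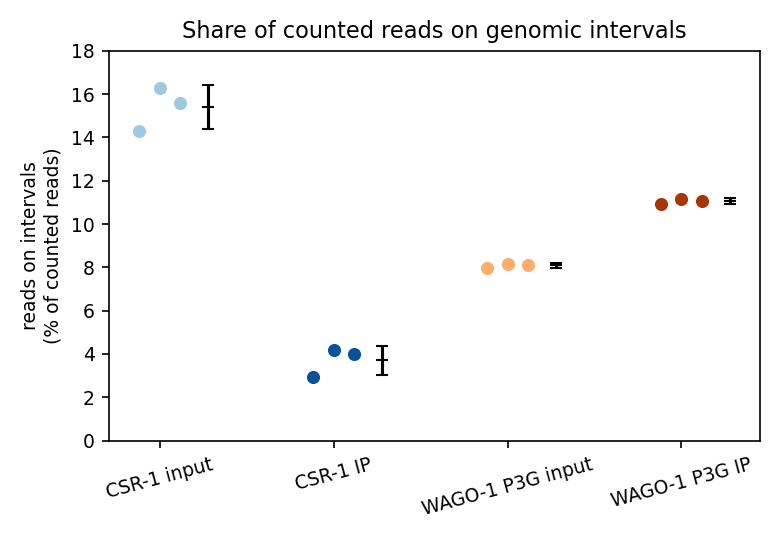
Share of counted reads on genomic intervals (y axis, % of counted reads, from 0) in each library, by group (x axis); points are libraries and bars the mean ± SD, n = 3. The CSR-1 IPs (mean 3.70%) lie below their inputs (15.4%), and the WAGO-1 P3G IPs (11.06%) lie above theirs (8.09%).

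Recovery with CSR-1 was asked by setting the CSR-1 IPs against their inputs. Most genomic intervals were lower in the IP, at a median log2 fold change of -1.83, while gene identifiers went in both directions at a median of 0.27 (-0.17 with library totals alone, -0.19 with all libraries thinned to the smallest). The exceptions among intervals included 3 adjoining intervals at plg-1 on chromosome III. In the reference strain plg-1, a mucin gene of the male copulatory plug, carries an insertion of the Cer1 retrotransposon. The interval III:8852596-8853087 (+), which overlaps plg-1 in part, rose from 15.3 ± 0.683 to 111.9 ± 5.23 CPM, a fitted 9.78-fold (log2 3.29 ± 0.24 SE, n = 3 and 3, edgeR adjusted p = 5.71e-12). Its neighbours III:8860969-8861460 (+) and III:8853088-8860968 (+) rose by log2 2.87 ± 0.25 and 1.66 ± 0.19. The former has the same length as the first interval, 492 bp, so that pair may share reads.

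Above the 20 CPM limit, the other intervals with the largest rises lay within the spans of coding genes, which are not known to be the source of their reads. III:11238924-11239014 (+) in aakb-2, a regulatory subunit of the AMP-activated kinase, rose from 45.2 ± 9.36 to 189.6 ± 9.82 CPM (log2 2.52 ± 0.17). II:11452706-11452951 (-) in rsp-2, an SR splicing factor, rose by log2 1.54 ± 0.26, and V:124224-124316 (-) in W03F9.1 by 1.22 ± 0.29. Among intervals above that limit, the steepest fall was at IV:5717456-5717543 (-), which overlaps 4 piRNA genes and fell from 46.8 ± 8.04 to 2.37 ± 1.19 CPM (log2 -3.95 ± 0.38). IV:12925373-12925435 (-), in no RefSeq gene, fell from 251.3 ± 33.5 to 18.3 ± 5.51 CPM (log2 -3.37 ± 0.17). X:339292-340372 (-) in C04E7.3, III:2295114-2295194 (+), IV:15556849-15557985 (+) in Y105C5A.2 and I:11060042-11060581 (+) in Y52B11A.18 fell by log2 -2.87 to -2.99. Among identifiers, WBGene00013553 rose from 15.9 ± 8.37 to 692.5 ± 27 CPM (log2 5.85 ± 0.20) and WBGene00185088 by log2 5.69 ± 0.16. WBGene00018418 fell from 80.5 ± 4.79 to 1.23 ± 0.813 CPM (log2 -5.48 ± 0.35) and WBGene00020566 by log2 -5.35 ± 1.08.

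Of 52 intervals overlapping structural or short RNA genes, 34 were called lower and 1 higher, at a median log2 of -1.61 (33 and 1 adjusted over the list alone; camera adjusted p = 3.76e-06 against all features, and adjusted p = 0.0474 with an estimated correlation). Of the other intervals 75.2% were lower, at a median of -1.84, and against them, a test added after the values were seen here and below, this class did not pass (camera adjusted p = 0.271). The 1 that rose was IV:15390132-15390490 (-), which overlaps the piRNA gene 21ur-15061, by log2 2.18 ± 0.54, and it was chosen after its values were seen. Of 5 intervals in meiotic prophase genes, 4 were lower and the fifth was not called (4 adjusted over the list alone), as were 74.8% of the other intervals, and against those the list did not pass (camera adjusted p = 0.305). Among the 4 were the 3 intervals of zim-1, which codes for a zinc-finger protein that binds chromosome pairing centres, with log2 -1.55 to -1.69. These 3 lie close together on the same strand and may not be separate instances, here and below. IV:10549140-10549474 (+) among them also overlaps the pseudogene T07G12.14. The fourth was in brc-1, the BRCA1 ortholog (log2 -1.86 ± 0.23). That interval is 1 of 46 of the same length, 1242 bp, with a median of -1.90, and its reads are not known to come from brc-1. Of 4 intervals in published WAGO-silenced genes, 4 fell, the direction of 962 of 1286 intervals (4 adjusted over the list alone), with log2 -1.80 to -2.58 for the 3 in the helicase gene eri-6. The interval in sid-1, a gene for a double-stranded RNA channel, lay below the 20 CPM limit, held 1 count in the CSR-1 IPs and was lower by a ratio of 41 (95% counting interval 4.58 to 1938; fitted 21.5-fold). II:10883644-10884141 (-) in egg-3, needed at the egg-to-embryo transition, rose by log2 1.95 ± 0.55 and II:11877467-11877540 (+) in the topoisomerase gene top-2 by 1.30 ± 0.44. These rises rest on 6 and 10 counts in the CSR-1 inputs, and the calls ended in 1 and 3 of 28 alternatives. The interval in the ribosomal protein gene rpl-42 fell by 1.64 ± 0.31 on the log2 scale, and the interval in the collagen gene col-186 had log2 -2.53 ± 0.83, a call that ended without CSR-1 input A (log2 -2.28, adjusted p = 0.0517 from edgeR).

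In all, edgeR called 4014 identifiers higher and 2671 lower, and 49 intervals higher and 962 lower (50 and 968 adjusted over the list alone). As a class the intervals were lower than other features (camera adjusted p = 1.23e-26, and adjusted p = 0.0474 with an estimated correlation). With the preset correlation, 5 of the 10 splits of the samples described below, the real one among them, called as many interval sets. The calls are relative to a scaling: with library totals alone the median of all 10822 features moved from -0.08 to -0.52, and 42.6% of calls were higher in place of 52.8%. Input RNA went through a small RNA enrichment kit and IP RNA did not, so IP against input also holds that step.

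The WAGO-1 P3G IPs were set against their inputs in the same way. Most genomic intervals were higher, at a median log2 of 1.07, against -0.12 for gene identifiers. The identifier median had no stable sign: it was 0.19 without WAGO-1 P3G input B, 0.17, 0.19 and 0.18 without IP A, B or C, and -0.01 with median-of-ratios factors. The interval median was 1.35 to 1.42 without those libraries. V:3106927-3107051 (-) in str-68, of a chemoreceptor family, rose from 13.6 ± 3.50 to 66.2 ± 11.5 CPM, a fitted 7.33-fold (log2 2.87 ± 0.30 SE, n = 3 and 3, edgeR adjusted p = 9.55e-09). IV:17031209-17031322 (-), beside nhr-229, rose from 35.0 ± 1.87 to 137.1 ± 18.6 CPM (log2 2.56 ± 0.24). V:6719164-6719359 (+), beside srg-30, rose from 52.2 ± 10.9 to 183.2 ± 12.8 CPM (log2 2.40 ± 0.22).

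V:13124100-13125216 (+), IV:13802472-13803429 (+) and I:62624-62684 (-) in Y48G1C.5 rose by log2 2.76, 2.55 and 2.55. A set of intervals nearly vanished from the IP. IV:12925373-12925435 (-) fell from 465.8 ± 21.7 to 0.864 ± 0.289 CPM (log2 -8.39 ± 0.22). At the right end of chromosome I, where the ribosomal RNA gene repeats lie, 3 intervals fell: I:15061534-15061702 (-) from 522.7 ± 76.6 to 3.40 ± 0.714 CPM (log2 -6.65 ± 0.24), I:15068731-15068899 (-) by log2 -6.55 ± 0.23 and I:15071824-15071991 (-) by log2 -6.32 ± 0.20. They are 169, 169 and 168 bp long with like CPM, so they may share reads and not be 3 separate measurements. V:4051532-4052132 (+) in C49G7.14 and X:14966395-14966547 (+) in F45B8.5 fell by log2 -5.97 and -5.83. Among identifiers, WBGene00003585 rose by log2 3.17 ± 0.43 and WBGene00018203 by 2.71 ± 0.30. WBGene00010102 fell from 693.5 ± 37.7 to 3.20 ± 0.511 CPM (log2 -7.16 ± 0.16) and WBGene00017225 by log2 -6.62 ± 0.19.

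Intervals overlapping structural or short RNA genes moved against the other intervals, with 9 of 52 higher, 29 lower and a median log2 of -2.38 (9 and 29 adjusted over the list alone; camera adjusted p = 0.00187 against all features, but adjusted p = 0.106 with an estimated correlation). In the added test against the other intervals, at a median of 1.10, camera gave adjusted p = 7.88e-20, and adjusted p = 0.00560 with an estimated correlation. All 5 intervals in meiotic prophase genes were higher (5 adjusted over the list alone), as were 54.8% of the other intervals, and against those the list did not pass (camera adjusted p = 0.0679). The zim-1 intervals rose by log2 1.64 to 1.97 and the brc-1 interval by 1.16 ± 0.23, beside a median of 1.39 for the 46 intervals of its length. The interval shared by lab-1 and T05F1.11 was the weakest, at 1.08 ± 0.47 (adjusted p = 0.0451 from edgeR), and leaving out any of the 3 WAGO-1 P3G inputs ended its call (log2 1.05 to 1.35), as did library totals alone (0.49). Of 4 intervals in published WAGO-silenced genes, 4 rose, the direction of 707 of 1286 intervals (4 adjusted over the list alone), the 3 of eri-6 by log2 1.10 to 2.04 and that of sid-1 by 1.66 ± 0.38. With library totals alone 2 of the eri-6 calls ended, at log2 0.99 and 0.50. The rpl-42 interval rose from 70.8 ± 9.47 to 163.2 ± 9.17 CPM (log2 1.80 ± 0.20). The col-186 interval, with 3 counts in the inputs, was higher by a ratio of 3.18 (95% counting interval 1.07 to 15.5; fitted 4.74-fold). In ZK402.5, an ERGO-1 class target, 3 counts were left in the IPs, lower by a ratio of 64.6 (95% counting interval 15.5 to 378; fitted 32.7-fold). The top-2 interval, with 3 counts in the inputs, was lower by a ratio of 9.08 (1.55 to 37.8; fitted 5.49-fold), and was not called when adjusted over the list alone. The call ended when any of 9 of the libraries was left out, all but CSR-1 input A, WAGO-1 P3G input A and WAGO-1 P3G IP C (log2 -1.18 to -2.50).

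In all, edgeR called 2987 identifiers higher and 3526 lower, and 707 intervals higher and 84 lower (685 and 82 adjusted over the list alone). As a class the intervals were higher than other features (camera adjusted p = 5.56e-10, but adjusted p = 0.106 with an estimated correlation). With library totals alone the median of all features moved from 0.12 to -0.48, that of the intervals stayed above it at 0.48, and the calls were 358 intervals higher and 127 lower, with 28.7% of all calls higher in place of 50.6%. The enrichment step of the inputs is a limit here too.

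Whether the baits recovered the same small RNAs was asked from the difference between their log2 enrichments, each against its own input. Genomic intervals had the higher enrichment with WAGO-1 P3G in 980 of 1286 cases and the lower in 81 (988 and 81 adjusted over the list alone), at a median difference of log2 2.90. The plg-1 intervals went the other way, with III:8852596-8853087 (+) at log2 -4.15 ± 0.45 (n = 3 per group, edgeR adjusted p = 9.42e-09), III:8860969-8861460 (+) at -4.15 ± 0.43 and III:8853088-8860968 (+) at -2.04 ± 0.32. The outer pair, of equal length, may share reads and be closer to a single measurement. Within the WAGO-1 P3G strain the outer pair had log2 -0.86 ± 0.31 and -1.28 ± 0.30, and the middle interval -0.37 ± 0.25 (adjusted p = 0.183 from edgeR). The first of these calls ended without WAGO-1 P3G input A or B, or without any of the 3 WAGO-1 P3G IPs (log2 -0.29 to -0.82).

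Above the 20 CPM limit the largest differences toward WAGO-1 P3G were IV:17031209-17031322 (-) at log2 4.83 ± 0.62, I:62624-62684 (-) at 4.79 ± 0.67, V:3106927-3107051 (-) at 4.77 ± 0.87, X:339292-340372 (-) at 4.77 ± 0.70, IV:13802472-13803429 (+) at 4.65 ± 0.42 and V:13124100-13125216 (+) at 4.60 ± 0.40. Toward CSR-1 the largest were X:14966395-14966547 (+) at log2 -5.45 ± 0.35 and I:15061534-15061702 (-) at -5.16 ± 0.31. I:15068731-15068899 (-), IV:12925373-12925435 (-), I:15071824-15071991 (-) and V:4051532-4052132 (+) followed at -5.07, -5.02, -4.89 and -4.89. Of these 6, 5 also fell in the CSR-1 IP, and X:14966395-14966547 (+) was not called there (log2 -0.38 ± 0.22). Among identifiers, WBGene00018203 and WBGene00009746 had differences of log2 4.54 and 4.51. WBGene00015347 reached -7.20 ± 0.36, with 47 ± 11 CPM in CSR-1 inputs, 944.7 ± 67.0 in CSR-1 IPs, 46.7 ± 6.50 in WAGO-1 P3G inputs and 5.74 ± 0.957 in WAGO-1 P3G IPs. WBGene00009013 reached -6.44 ± 0.53.

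In the meiotic prophase list 4 of 5 intervals leaned toward WAGO-1 P3G and the fifth was not called (4 adjusted over the list alone), as did 76.2% of the other intervals, and against those the list did not pass (camera adjusted p = 0.128). The values were log2 3.28 to 3.53 for zim-1 and 3.02 ± 0.32 for brc-1, beside a median of 3.31 for the 46 intervals of the length of the latter. The 4 intervals in published WAGO-silenced genes leaned the same way (4 adjusted over the list alone), those of eri-6 at log2 2.90 to 4.33, and so did the rpl-42 interval at 3.44 ± 0.38. Below the 20 CPM limit the sid-1 difference was 6.09 ± 1.25, with 1 count in the CSR-1 IPs. Toward CSR-1 lay the ZK402.5 interval, at -4.43 ± 1.06, and the top-2 interval, at -3.75 ± 1.24, a call that ended without WAGO-1 P3G input B (log2 -2.46). The germ granule list had 2 tested intervals, both in simr-1, which acts in piRNA-directed small RNA amplification, and they split. I:5980182-5981873 (-) had a difference of log2 2.14 ± 0.13, with CPM from 828.7 ± 55.4 to 268.2 ± 14.1 in CSR-1 libraries and from 1373 ± 45.1 to 1732 ± 14.9 in WAGO-1 P3G libraries. I:5981856-5982780 (-) had -2.92 ± 0.77, at 1.84 to 8.81 CPM in the group means. Its rise in the CSR-1 IP (log2 1.29 ± 0.52, adjusted p = 0.0309 from edgeR) ended without CSR-1 input A, CSR-1 input B or CSR-1 IP A (adjusted p = 0.0611 to 0.135 from edgeR). Its fall in the WAGO-1 P3G IP (log2 -1.63 ± 0.57) ended without WAGO-1 P3G input B (-1.04) or WAGO-1 P3G IP A (-1.19). Intervals overlapping structural or short RNA genes were split, with 19 higher and 22 lower (19 and 22 adjusted over the list alone), a median of -1.13 and a mean of -0.13. They did not pass against all features (camera adjusted p = 0.781), and in the added test against the other intervals, at a median of 2.94, they were lower (camera adjusted p = 6.93e-13, and adjusted p = 0.0144 with an estimated correlation).

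Features higher in both IPs were fewer than independence gives, 486 against 1387 (0.350 of it, odds ratio 0.150, 95% interval 0.135 to 0.167, Fisher's exact test, 2-sided, 12 tests). Features lower with CSR-1 and higher with WAGO-1 P3G numbered 2185 against 1240, and the reverse 2050 against 1355. Only 2 intervals were higher in both, against 26.9, and they were chosen after their values were seen. V:124224-124316 (-) in W03F9.1 had log2 1.22 and 1.03, and these calls ended in 2 and 3 of 35 alternatives. IV:2483382-2483436 (-) in Y69A2AL.2 had log2 0.61 ± 0.22 with CSR-1 and 1.83 ± 0.55 with WAGO-1 P3G, and the former turned to -0.09 with all libraries thinned to the smallest and ended without CSR-1 input C (0.57) or CSR-1 IP C (0.51). Across the features, which are not independent replicates, the enrichments had r = -0.323 and Spearman's rho = -0.441, part of which is the offset between the classes. Within identifiers r was -0.287 and rho -0.386, and within intervals -0.140 and -0.141. With no filter on low counts the overlap reversed to 1.76 times its expectation, over features with almost no reads. As a class the intervals leaned toward WAGO-1 P3G (camera adjusted p = 1.11e-23, and adjusted p = 0.0474 with an estimated correlation), and edgeR called 2689 identifiers higher and 4249 lower. With the preset correlation, all 10 splits of the samples described below called as many interval sets as the real one. The number of sets called therefore does not tell the real grouping from the others.

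**Figure D2:**
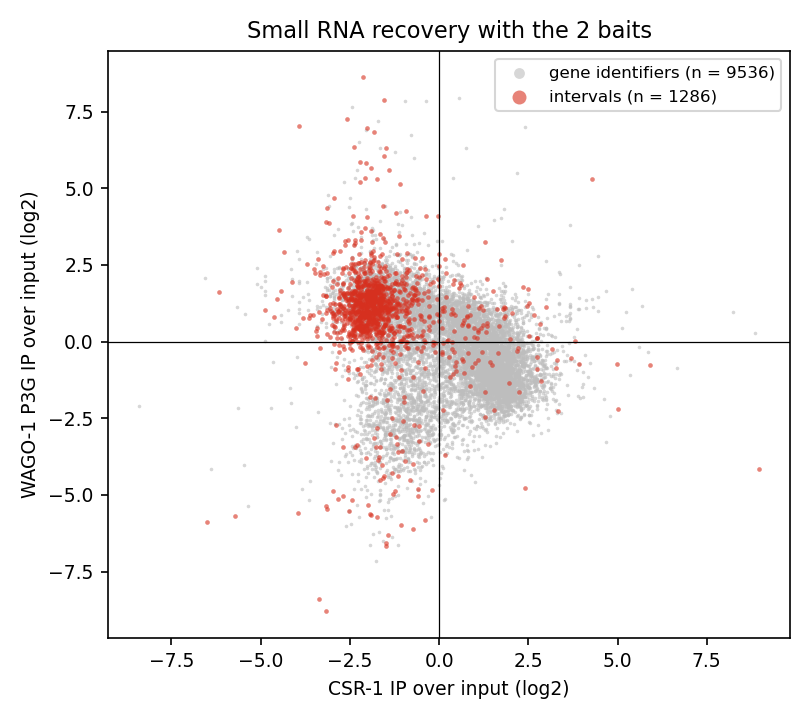
Log2 fold change of IP over input with CSR-1 (x axis) and with WAGO-1 P3G (y axis) for each tested feature; grey points are 9536 gene identifiers and red points 1286 genomic intervals. Most intervals lie left of 0 (median -1.83) and above 0 (median 1.07).

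The strains' extracts were compared before IP, WAGO-1 P3G input against CSR-1 input. Genomic intervals were lower in the WAGO-1 P3G inputs at a median log2 of -0.82, with 108 of 1286 higher and 539 lower (116 and 559 adjusted over the list alone). On chromosome V, 150 of 265 were lower and 14 higher, at a median of -1.27, and on chromosome II 58 of 195 lower and 28 higher, at a median of -0.20. The 8 most abundant intervals of the CSR-1 inputs were picked after their values were seen. Ranking by that side of the comparison favours intervals that are lower on the other. Of these 8, 7 were lower in the WAGO-1 P3G inputs. Among them V:17132108-17137381 (-), V:17137383-17141676 (-) and V:17142308-17143636 (-) lie side by side and may not be separate instances. V:17132108-17137381 (-), which holds the short noncoding gene Y102A5D.22, had 5968 ± 589 CPM in CSR-1 inputs and 870.0 ± 32.3 in WAGO-1 P3G inputs, a fitted 7.27-fold lower (log2 -2.86 ± 0.13 SE, n = 3 and 3, edgeR adjusted p = 4.58e-15). V:17421682-17428709 (-) went from 4650 ± 388 to 602.0 ± 33.4 CPM (log2 -3.03 ± 0.10).

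V:17137383-17141676 (-), whose span holds the microRNA gene mir-257, V:17142308-17143636 (-) and IV:913372-921243 (+), which holds F58H7.5, were lower by log2 -2.74 ± 0.14, -2.12 ± 0.13 and -2.34. V:18436471-18442343 (+), which holds ZK262.8, and III:13230129-13242682 (-), which holds Y43F4A.3, had log2 -1.65 and -1.90. The exception, V:11487340-11488176 (+) in T11F9.10, had 3522 ± 413 and 3578 ± 189 CPM in the inputs and was not called (log2 -0.06 ± 0.12, adjusted p = 0.728 from edgeR). Intervals higher in the WAGO-1 P3G inputs included III:971060-971258 (+) in R06B10.1 at log2 3.49 ± 0.56, the pair V:14761618-14764280 (+) and V:14764611-14765406 (+) in Y50E8A.14 at 2.79 ± 0.26 and 2.57 ± 0.37, and II:2151236-2151395 (-) at 2.55 ± 0.42. The steepest falls above the 20 CPM limit left few reads. III:6630737-6631713 (+) held 142 counts in CSR-1 inputs and 1 in WAGO-1 P3G inputs, lower by a ratio of 111.5 (95% counting interval 19.7 to 4433). X:16234996-16236011 (+) in F23A7.5 held 96 and 1, a ratio of 75.3 (13.2 to 3007). I:86089-86176 (-) in mtm-10 and Y48G1C.6 held 170 and 3, a ratio of 44.5 (15.0 to 218). II:13260794-13261023 (+) in Y48C3A.1 fell from 220.4 ± 19.1 to 3.90 ± 1.72 CPM (log2 -5.89 ± 0.45).

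Among identifiers, WBGene00004453 was higher, 185.0 ± 27 against 3.86 ± 1.45 CPM (log2 5.49 ± 0.34), as was WBGene00019448, from 2 counts, by a ratio of 29.9 (7.84 to 254). WBGene00015096 fell from 976.9 ± 53.2 to 3.90 ± 1.72 CPM (log2 -8.03 ± 0.23), and WBGene00004196, with 3 counts left, by a ratio of 72.5 (24.5 to 354). In the meiotic prophase list 4 of 5 intervals were lower and the fifth was not called (4 adjusted over the list alone), against 41.8% of the other intervals, and the list did not pass against those (camera adjusted p = 0.383). The zim-1 intervals were lower by log2 -1.17 to -1.73, and the brc-1 call (log2 -0.82 ± 0.28, beside a median of -0.91 for the 46 intervals of its length) ended without CSR-1 input C (-0.72) or WAGO-1 P3G input A (-0.65). Of the eri-6 intervals, I:4467100-4467296 (+) was lower by log2 -2.58 ± 0.41, the 1 call of that list of 4 (3 lower and 1 higher adjusted over the list alone). Higher were the first simr-1 interval (log2 0.65 ± 0.09) and the rpl-42 interval (1.03 ± 0.30), the latter not without CSR-1 input A (0.77). Of 52 intervals overlapping structural or short RNA genes 5 were higher and 7 lower (4 and 7 adjusted over the list alone), at a median of 0.26 and a mean of -0.09. They did not pass against all features (camera adjusted p = 0.633), though fry, which tests the set by itself, gave adjusted p = 0.0203. In the added test against the other intervals, at a median of -0.87, they were higher (camera adjusted p = 0.0248, but adjusted p = 0.416 with an estimated correlation). Intervals of 1000 bp or more were lower, 257 of 421 against 30 higher, at a median log2 of -1.15 (camera adjusted p = 3.40e-20 against all features and 1.55e-06 against the other intervals, but adjusted p = 0.0997 and 0.588 with an estimated correlation). Those under 200 bp did not pass against all features (camera adjusted p = 0.0756), and were higher than the other intervals (camera adjusted p = 0.000272, but adjusted p = 0.374 with an estimated correlation). As a class the intervals gave camera adjusted p = 3.47e-10, but adjusted p = 0.106 with an estimated correlation, and edgeR called 2023 identifiers higher and 1481 lower.

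**Figure D3:**
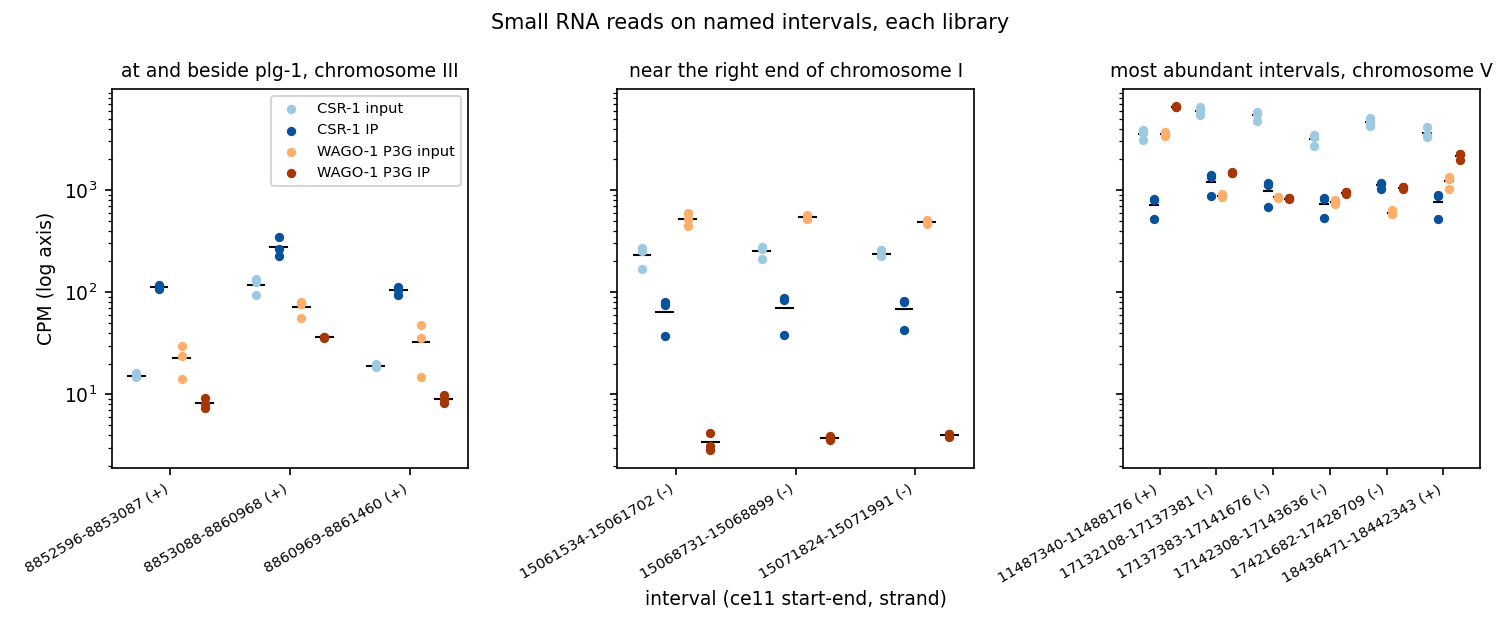
Small RNA reads (y axis, CPM, log axis) on named intervals (x axis, ce11 coordinates and strand) in each library; points are libraries coloured by group and bars the group mean, n = 3. Of the 4 groups, the CSR-1 IPs are highest at plg-1 (111.9 CPM at the first interval) and the WAGO-1 P3G IPs lowest at the end of chromosome I (3.40 CPM at the first). On chromosome V, at intervals picked for abundance in the CSR-1 inputs, those inputs are highest. The exception is the first interval, in T11F9.10, where the WAGO-1 P3G IPs are highest.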

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

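Of the tests in this part, those on normalization and on strain for the inputs, on depth, and on extract carried over into the CSR-1 IP were chosen after the result was seen. The others were set before, that on same-length intervals once such intervals had been noticed in the data.

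The baits differed in the effect of IP on genomic intervals, by the test of the difference itself: 980 intervals had a higher enrichment with WAGO-1 P3G than with CSR-1, and the median difference over intervals was log2 2.90. A difference in depth is argued against, since with all libraries thinned to the smallest the median difference was 3.002. For the interval shares, a few abundant intervals are argued against as well. Without the 20 most abundant, the share of the CSR-1 IPs was still 0.245 of that of their inputs. That of the WAGO-1 P3G IPs was 7.84%, against 5.91% in their inputs. The count of 980 and the median weigh each interval alike, so these shares do not bear on them. Extract carried over into the CSR-1 IP stays open and may set the residual level, since over the intervals the CSR-1 IP correlated with its own input at r = 0.877 and with the other strain's input at 0.715. Proportional recovery of part of these small RNAs by CSR-1 would give the same correlation, and bait, strain and genotype differ together, so that a difference between the Argonautes remains a hypothesis.

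Genomic intervals were also lower in the WAGO-1 P3G inputs than in the CSR-1 inputs. Normalization is argued against, since with library totals alone the median was log2 -0.73. For the interval shares, a few abundant intervals are argued against, since without the 20 most abundant the ratio of the shares was 0.558. A difference of strain and genotype could account for it but cannot be told apart from how each strain was grown and extracted, because each strain has its own 3 inputs, and the exact permutation test, 2-sided, gave p = 0.1, the smallest that 3 against 3 allows.

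Long intervals of the same length changed alike. Groups of at least 8 intervals of equal length, of 1000 bp or more, numbered 6, with 107 intervals. The mean SD of the log2 fold changes within a group was 0.275. The lowest of 1000 draws of intervals of like abundance had 0.866 and their median was 1.195. The draws were not matched on length. Of intervals of 1000 bp or more 90.5% were lower in the CSR-1 IP, against 67.2% of the others, so the draws do not single out equal length. Copies still differed in level, with a coefficient of variation of 0.255 to 0.627 within groups in the WAGO-1 P3G IPs. Reads shared between near-identical copies may tie these intervals to each other, which would make them fewer independent measurements than their number. Elements of equal sequence that behave alike would give the same value, and the table does not separate the explanations.

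Single intervals were singled out by the same test of the difference between baits. At plg-1 the difference was log2 -4.15 for III:8852596-8853087 (+), -2.04 for III:8853088-8860968 (+) and -4.15 for III:8860969-8861460 (+), against the direction of most intervals. At the right end of chromosome I it was -5.16 for I:15061534-15061702 (-), -5.07 for I:15068731-15068899 (-) and -4.89 for I:15071824-15071991 (-). The outer plg-1 intervals are both 492 bp long and those of chromosome I 168 or 169 bp. Intervals within each of these sets may therefore share reads, and no sequence was compared. The 2 intervals in simr-1 split, at 2.14 for I:5980182-5981873 (-) and -2.92 for I:5981856-5982780 (-). Reads that could not be assigned to a single feature, which no comparison uses, made up 2.81 times as large a share of totals in the WAGO-1 P3G IPs (0.145%) as in their inputs (0.0514%). Reads on no feature fell there from 73.3% to 31.9% of totals, and the share on gene identifiers rose 2.46 times. A rise was thus not seen in ambiguous reads alone, and whether the 2 rises are linked was not tested. For the CSR-1 IPs over their inputs the ambiguous share had a ratio of 0.925 and the identifier share 2.00.

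For each comparison the 6 samples, or same-letter differences, split into 3 and 3 in 10 ways, too few for a share under 0.05. For features called by edgeR, 1 of 10 splits, the real one, reached the real count in each comparison: 7696 for the CSR-1 IP, 7304 for the WAGO-1 P3G IP, 7999 for the difference and 4151 for the inputs. The highest of the other splits called 0 in each. At an unadjusted p under 0.05 the highest others had 763, 143, 17 and 492 features. For interval sets called by camera with the preset correlation, the real counts were 10, 10, 9 and 8 and the highest others 10, 9, 9 and 6. As many sets as in the real split came from 5, 1, 10 and 1 of the 10 splits. Each other split sets 2 samples of one group and 1 of the other against the reverse, so it still holds part of the real difference. The rest of that difference lies within the mixed groups and widens their spread. Few features could therefore be called in these splits, and their counts of 0 do not weigh for the real grouping.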

How the results depend on the processing

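Thinning, the omission of both CSR-1 libraries lettered A and every value with the filter run again were chosen after seeing the data, as was holding the tested features when a library is left out. Of 6181 alternative values of named features, 6009 kept direction and side of the threshold, 115 lost the call, 54 gained it and 3 reversed. Of 716 set tests, 683 kept both, 30 lost the call and 3 gained it. With an estimated correlation 10 sets passed in place of 37, and against the other intervals alone 13 of 36 passed with the preset correlation and 2 with an estimated one. The causes of the changes below were not tested, except where the number of features tested shows them. The inputs are the shallow side of each comparison, and in simulated data 50 to 81 of 100 changes of 2-fold were recovered.

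Library totals alone gave 1904 features higher in the WAGO-1 P3G IP (3694 in the report's fit), 358 intervals higher (707) and 127 lower (84), and V:17137383-17141676:- in WAGO-1 P3G IP against input reversed to log2 -0.0450 (not past the threshold). No filter gave 142 intervals higher with CSR-1 (49), 5559 features higher (3694) and 1184 intervals higher and 155 lower with WAGO-1 P3G, and the overlap reversed from 0.350 to 1.76 of its expectation, with 45440 features tested. At least 5 CPM in 3 libraries gave 79 intervals higher with CSR-1. Only the libraries compared gave 32 there, and 67 intervals higher in the WAGO-1 P3G inputs (108).

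Thinning gave 2597 features (4063) and 24 intervals higher with CSR-1, 2280 features and 413 intervals higher with WAGO-1 P3G, and 35 intervals lower in the difference (81). IV:2483382-2483436:- in CSR-1 IP against input reversed to log2 -0.0927, and to -0.236 with the filter run again. That fit tested 6752 features, 577 of them intervals, and gave 2268 features and 8 intervals higher and 545 intervals lower with CSR-1. With WAGO-1 P3G it gave 2038 features higher and 2338 lower, 334 intervals higher and 34 lower. The difference had 2345 features higher and 2604 lower, 517 intervals higher and 21 lower, and the inputs had 357 intervals lower.

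Leaving out each library in turn, with the tested features held, gave for CSR-1 3819 to 4069 features higher, 3096 to 3661 lower, 40 to 51 intervals higher and 889 to 963 lower. For WAGO-1 P3G it gave 3205 to 4355, 2856 to 3673, 583 to 838 and 70 to 87. For the difference it gave 3370 to 3943, 3723 to 4390, 910 to 1019 and 62 to 81. For the inputs it gave 1703 to 2259, 1779 to 2170, 92 to 117 and 491 to 550. The overlap ranged from 0.323 to 0.431 of its expectation and the sets passed from 36 to 37. The interval share changed by -12.2 to -11.2 points with CSR-1, by 2.91 to 3.03 with WAGO-1 P3G and by -7.85 to -6.86 between inputs. With the filter run again, 8473 to 13013 features were tested, and CSR-1 had 3399 to 4410 features higher, 17 to 110 intervals higher and 742 to 1186 lower. WAGO-1 P3G then had 3076 to 5031 features higher, 534 to 1021 intervals higher and 50 to 108 lower. The difference had 710 to 1232 intervals higher and 47 to 94 lower, and the overlap was 0.311 to 0.510. Without both CSR-1 libraries lettered A, 3881 features were higher and 3380 lower with CSR-1, 3919 and 3718 with WAGO-1 P3G, 3549 and 4306 in the difference and 1942 and 1984 between inputs.

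With the replicate letter as a block, 4130 features were higher and 3733 lower with CSR-1, 3862 and 3675 with WAGO-1 P3G, 3733 and 4443 in the difference and 2176 and 2118 between inputs. Same-letter correlations of residuals were 0.31, 0.20 and 0.04 for CSR-1 and 0.02, 0.0014 and -0.0095 for WAGO-1 P3G. Between different letters they were -0.257 to 0.111 for CSR-1 and -0.034 to 0.033 for WAGO-1 P3G. The letters A and B of CSR-1 thus gave some sign of pairing, and those of WAGO-1 P3G gave little. Residuals of a group offset each other, so these values are not independent.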

Other observations

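Some intervals of equal length, seen after the data were examined, repeated across the genome. The 21 tested intervals of 1611 bp, close to the length of the Tc1 transposon although no sequence was compared, lay on 6 chromosomes and held 3046 ± 164 CPM in sum in the CSR-1 inputs and 1097 ± 26.5 in the WAGO-1 P3G inputs (SD, n = 3 each). All 21 were lower in the CSR-1 IP. In the WAGO-1 P3G IP 13 were called higher, at a fitted median log2 of 0.57, but their sum did not rise there (1073 ± 11.0 CPM). The 12 intervals of 2337 bp, close to the length of Tc3, held 2919 ± 241 CPM in CSR-1 inputs, 3474 ± 137 in WAGO-1 P3G inputs and 7793 ± 305 in WAGO-1 P3G IPs. All 12 were higher in that IP, at a median log2 of 1.76, and lower in the CSR-1 IP, while 1 passed the edgeR test between the inputs and was higher there. With reads perhaps shared between copies (mean SD within groups 0.275), each group may be closer to a single measurement.

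The 46 intervals of 1242 bp and the 12 of 1241 bp were all lower in the CSR-1 IP, at median log2 of -1.90 and -1.99, and all higher in the WAGO-1 P3G IP, at 1.39 and 1.42. Of the 8 intervals of 1286 bp, 8 were lower in the WAGO-1 P3G inputs, at a median log2 of -1.90. Of the 8 of 1252 bp, 6 were, at -1.71.

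Gene identifiers at least 2-fold higher in the WAGO-1 P3G IP, 2250 in number, were lower in the CSR-1 IP at a median log2 of -1.36, with quartiles of -1.84 and -0.55. The intervals had a median of -1.83 there, with quartiles of -2.23 and -1.31.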
